A study of Homo sapiens with 24 samples.

How the data were processed

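H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 12 xenograft models of triple-negative breast cancer. Such a model is a patient's tumour passaged in mice, here by injection into the mammary fat pad per the labels. The series held 24 samples, 12 of H3K27ac ChIP and 12 of input DNA. Each ChIP sample came with 1 peak list, and the input samples were not analysed here. Models are called model 1 to model 12, a number that only names a sample. Each model had 1 library, so no value within a model has a replicate error, and spreads are between models.

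Per the labels, tumour tissue was pulverised, crosslinked and sonicated, and sequencing libraries were made from small amounts of precipitated or input DNA. Per the submitters' processing notes, BWA 0.7.17, Picard and MACS2 2.1.2 were used with the human genome build hg19. The role and order of these tools are not given in the sources used here. Whether the input library served as control and whether mouse reads were removed are likewise not given in the sources used here. The deposited files hold 1 list per sample, so peaks were called per sample and not on pooled samples.

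Each deposited peak has a position, a fold enrichment (a ratio over the background that the authors' peak caller estimated) and the authors' −log10 p and −log10 q values. The deposited score column was not used. The lowest deposited −log10 q was 2.01, just above that of a q-value of 0.01. Fold enrichment and −log10 p are each list's own values and were used mainly to describe, rank or filter peaks within a list. Fold was also averaged over the 12 lists to name core regions and set against that of another list for models 1 and 2, although the lists were not scaled to each other. The deposited lists give no read counts, so the depth of each library is unknown and no counting error of a peak could be given. A longer list can come from deeper sequencing, a stronger precipitation or more acetylated sites.

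Peaks on chromosomes 1 to 22 and X were analysed. This restriction was made after the lists were opened, since the plan named all deposited peaks. Coordinates are those of hg19, counted from 1, and bands came from the hg19 cytoband table in circlize 0.4.16. The gene table at hand was of another build, so no gene was assigned to a region. The planned rules that need an hg19 annotation were therefore not run, and the fallback written in the plan was used. It names the 5 regions in all 12 models with the highest mean fold, the single-model region of highest fold in each model, the 10 domains in the most models, and each model's longest-covered domain found in no other model.

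The peaks of the 12 models were merged into regions when they overlapped or touched, and a model had a region when at least 1 bp of a peak lay in it. Shares of regions carry 95% Wilson intervals, which cover counting error only. For pairwise overlap, lists of equal length were made from the 12715 peaks of highest −log10 p in each model, 12715 being the length of the shortest list. The Jaccard index, the base pairs shared by both lists over those in either, was computed with bedtools 2.31.1 for the 66 pairs. Sequencing run was read from the deposited file names, which gave 3 runs of 7 models (run A: models 1, 2, 3, 4, 5, 7 and 8), 3 models (run B: 6, 11 and 12) and 2 models (run C: 9 and 10). The same-run and different-run indices were compared with a two-sided permutation test of 100000 reassignments of runs to models.

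Broad domains were made by joining the peaks of a model at most 12.5 kb apart and keeping the 500 domains with most base pairs under peaks in each model. They come from peak lists and not from read signal, and are not called super-enhancers.

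Several analyses were chosen after the data were examined. These were the regions found in exactly 2 models, the shares per chromosome, the strongest and weakest 1000 peaks of each list, the 3 relations across models, the random placement of peaks, the widths of single peaks, and the domains found only in a pair of models. The expected number of regions only in a pair was the product of a factor for each model, fitted to the counts of all other pairs. In an alternative, the factor of each model was fitted with its partner left out, and the 3 pairs with the highest ratios took no part in the fits. An earlier fit that included the pair itself was dropped because it understated a simulated excess. Intervals of the ratio came from 1000 bootstrap resamples of 5 Mb blocks. Chromosome shares and peak strength were compared over the 12 models with two-sided exact sign-flip permutation tests, with Benjamini-Hochberg adjustment over 23 chromosomes. Correlations across models carry permutation tests, two-sided, with 100000 resamples, or with all orders for the models of run A. In 20 random placements, the peaks of each model were shifted together along each chromosome.

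The steps were tested on simulated data. Among 100000 simulated regions, the counts of regions in all 12 models and in 1 model were recovered (100%). Simulated regions were too far apart to merge, so the merging of neighbours was not tested. A pair made to share 8 times the expected regions was returned at 8.15, with 1.518 as the highest ratio of another pair. With the partner left out, the simulated pair was returned at 8.15 and an unaltered pair at 1.11. Both fits thus returned the same ratio for the simulated pair, while for models 1 and 2 they gave 91.24 and 5.41. The simulation therefore did not test what separates the fits in the real data. It cannot show which of the real ratios is nearer the true excess. In 200 simulated matrices the run test gave a p under 0.05 in 3.0% with no run effect and in 100% with an effect of 0.1 in the Jaccard index. The simulated indices varied less between pairs than the real ones (SD 0.088), so the 100% is not the power in these data. Alternatives fixed before the data were examined, for the planned results only, were a −log10 q of at least 5, equal-length lists and a 50% coverage rule for the sharing of regions, other list lengths and rankings for the Jaccard index and, for domains, equal-length lists, 300 or 1000 domains per model and a joining distance of 5 kb. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.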

Results

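H3K27ac peak lists of 12 triple-negative breast cancer xenograft models were compared to ask how far the acetylated regions differ between tumours, the subject the series title gives. The labels name no subgroup, so the models formed 1 group of 12. The lists held 38638 ± 10408 peaks (mean ± SD, n = 12) on chromosomes 1 to 22 and X. Model 7 had the fewest peaks, 12715, and model 1 the most, 49758. Model 4 had 49208 peaks, model 12 had 46921, and model 11, the next shortest list after model 7, had 28167. Peaks covered 28.48 ± 10.93 Mb per model, from 5.32 Mb in model 7 to 44.74 Mb in model 10. The median fold enrichment in a list varied less, at 6.77 ± 0.57, from 6.0 in model 2 to 7.8 in model 10. The highest −log10 p was 76.1 in model 7 and 299.6 in model 10.

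The 12 models shared a core of 5297 acetylated regions, and a larger number of regions had a peak called in 1 model only. A region not called in a model is not shown to lack acetylation there. Of 131108 merged regions, the core made up 4.04%, while 76810 (58.59%) had a peak in 1 model and 49001 in 2 to 11 models. The fold of a region in a model was that of its highest peak there, averaged over the models with a peak. The median of this fold over regions was 16.28 in the core and 5.28 in single-model regions, and the median widths were 2507 and 283 bp. A wide core region can hold several peaks of a model, and taking the highest can raise its fold by construction. Merging the peaks of 12 models widens a core region by construction, so widths were also compared for single peaks. The median peak width in a model was 915 ± 409 bp (SD, n = 12) in core regions and 262 ± 45 bp in single-model regions, wider in the core in 12 of 12 models. Wider peaks overlap others more easily and so fall in the core more easily, so the way the core was defined can set part of this difference too. The core covered 16.18 Mb of the 113.9 Mb in all regions and took 34.74% ± 11.64 (SD, n = 12) of the base pairs under peaks in a model. That share was 25.5% in model 4 and 69.8% in model 7. In 20 random placements of the peaks, which could put them anywhere on a chromosome, no region fell in all 12 models. That is a low bar and does not show that the core is particular to these tumours. A further 2035 regions were in every model except model 7, and without model 7 the other 11 models shared 7332 regions. With lists of equal length the core held 2626 regions and the single-model part 14636, and without models 4 and 12 the single-model part held 49686. With the rule that peaks cover at least 50% of a region the core held 116.

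**Figure D1:**
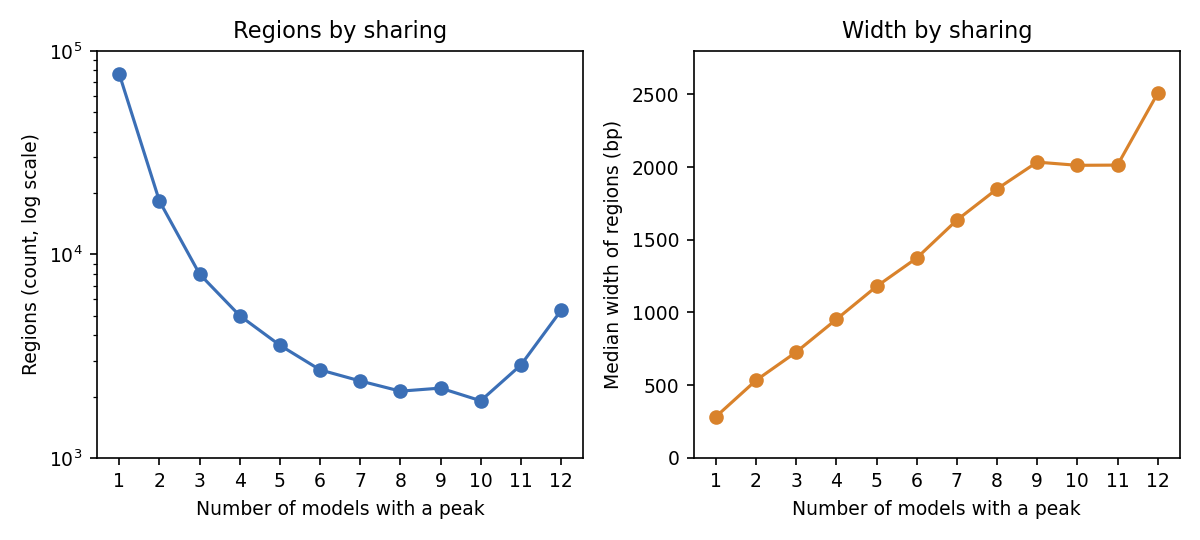
The left panel plots the number of merged H3K27ac regions (log scale) and the right panel their median width in bp, against the number of the 12 models with a peak. Regions in 1 model numbered 76810 with a median width of 283 bp, and regions in all 12 models numbered 5297 with a median width of 2507 bp, a width that merging the peaks of more models raises by construction.

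The core region with the highest mean fold lay at chr2:208026131-208032433 (2q33.3), with a fold of 35.0 ± 11.1 (SD, n = 12) and a range from 18.3 to 52.8. The region at chr2:70366687-70369759 (2p13.3) had a fold of 34.1 ± 9.9, and that at chr10:32634309-32636800 (10p11.22) 33.9 ± 12.2. The region at chr17:80414413-80417688 (17q25.3) followed with 33.6 ± 10.2, and that at chr6:64281022-64285542 (6q12) with 33.5 ± 11.9. These means differed by less than their spread between models. Differences between the regions within a model were not examined, so their order is not resolved here. Each of the 5 regions had a peak in all 12 models at a −log10 q of at least 5 and in the equal-length lists.

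Models 4 and 12 held 49.5% of all single-model regions. Model 4 had 19088, or 43.63% of its regions (95% interval 43.16% to 44.09%), and model 12 had 18934, or 47.37% (46.88% to 47.86%). Model 10 followed with 7596 single-model regions (20.42% of its regions), and model 5 had 5700 (22.89%). Model 2 had 1774 (5.92%), model 8 had 1897 (7.48%) and model 7 had 224 (2.62%). The low count of model 2 depends on model 1 being in the set. Of the 5438 regions of model 2 that models 3 to 12 lack, 3664 were also called in model 1. Model 1 had 9227 such regions, of which 5563 were single-model regions. In equal-length lists both models together held 36.5%, with 3307 regions in model 12 and 2036 in model 4, and model 5 was next at 1877 and model 11 at 1776.

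**Figure D2:**
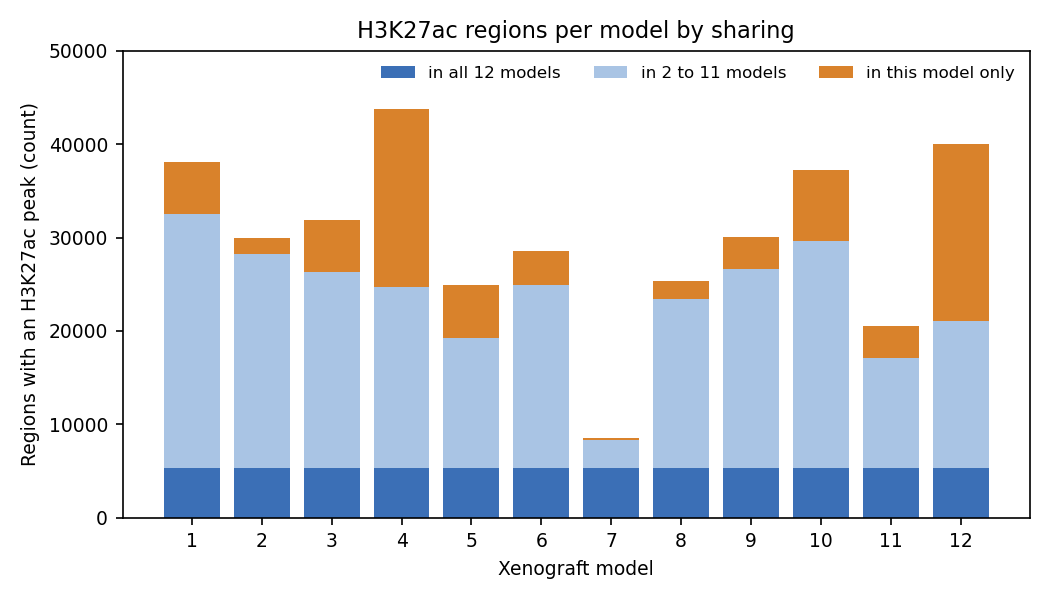
Stacked bars give the number of merged H3K27ac regions in each of the 12 xenograft models, divided into regions in all 12 models, in 2 to 11 models and in that model only. Models 4 and 12 have the most single-model regions, 19088 and 18934, and model 7 has the fewest, 224.

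Some single-model regions had a fold as high as the mean folds of the named core regions, each fold being that list's own. Model 4 had a fold of 37.0 at chr9:97400448-97402498 (9q22.32), with no peak in the other 11 models. Model 10 had a fold of 35.5 at chr11:75587695-75590625 (11q13.5), model 9 a fold of 35.2 at chr2:81708022-81709665 (2p12), and model 12 a fold of 33.2 at chr1:136890-140262 (1p36.33). Model 5 had a fold of 24.4 at chr11:1894810-1895399 (11p15.5), and model 6 a fold of 20.0 at chr4:16169017-16171689 (4p15.32). The strongest such regions of models 3 and 11 both had a fold of 19.6, at chr8:140748274-140749971 (8q24.3) and chr9:12950423-12953781 (9p23). That of model 8 was at chr13:34284838-34285993 (13q13.2) with a fold of 18.6, and that of model 7 at chr6:99280045-99280924 (6q16.1) with 12.9. The lowest values were 10.5 in model 1 at chr2:13697648-13698471 (2p24.3) and 9.0 in model 2 at chr10:5085634-5085880 (10p15.1). These folds have no replicate check, and their order between models was not tested.

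Chromosomes 19, 1, 16 and 22 held a larger part of the core than of the single-model regions. Chromosome 19 held 6.1% of core regions (95% interval 5.48% to 6.77%) and 2.57% ± 1.65 (SD, n = 12) of single-model regions, lower in 11 of 12 models. Chromosome 1 held 12.8% of the core and 9.41% ± 1.45 of single-model regions, lower in 12 of 12. Chromosomes 5, 8 and 18 went the other way, each in 11 of 12 models. Chromosome 5 held 3.47% of the core and 5.75% ± 1.31 of single-model regions, chromosome 8 held 3.38% and 5.19% ± 1.27, and chromosome 18 held 1.4% and 2.4% ± 0.7. For chromosomes 19, 1, 5, 8, 16 and 18 the adjusted p was 0.00562 in the exact sign-flip permutation test, and for chromosome 22 it was 0.00642. The test took the core share as fixed, so the counting error of that share is not in these p-values. Of 23 chromosomes tested, 6 had a lower and 8 a higher single-model share at an adjusted p under 0.05. In equal-length lists 3 and 2 did, so not all of the chromosomes named above passed there.

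The strongest acetylation of each tumour fell mostly in the core, and the weakest peaks rarely did. Of the 1000 peaks of highest −log10 p in a model, 76.2% ± 5.87 (SD, n = 12) lay in regions of all 12 models, from 66.5% in model 12 to 85.9% in model 7. Of the 1000 weakest, 11.97% ± 12.45 did, from 4.3% in model 10 to 50.8% in model 7, whose list was the shortest. The strongest peaks had the higher share in 12 of 12 models (exact sign-flip permutation test, two-sided, p = 0.000488, the smallest that 12 models allow). The core was defined from these same lists, and wider peaks overlap others more easily. The p-value therefore covers only how constant the direction was over models that share 1 core. Single-model regions took 0.35% ± 0.74 of the strongest peaks and 29.25% ± 16.7 of the weakest. Model 12 had the highest share among the strongest peaks, 2.6%, and model 4 the highest among the weakest, 62.4%.

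Models 1 and 2 had the most similar peak sets. In equal-length lists the Jaccard index of models 1 and 2 was 0.663, above 0.459 for models 6 and 10, the next pair. With windows of 500 bp around summits the 2 indices were 0.43 and 0.372. The median of the 66 pairs was 0.286 and their SD 0.088, with the lowest index, 0.149, between models 4 and 7. The highest index in random placements, the same low bar, was 0.0066. The 11 pairs with model 7 had a median of 0.192, and its equal-length list covered 5.32 Mb where that of model 10 covered 27.43 Mb. Models 8 and 9 had the highest mean index with the other models, 0.352 and 0.354, while models 12 and 7 had the lowest, 0.241 and 0.194. The short covered length of model 7 limits its index, and with summit windows its mean was 0.238, above 0.217 for model 12 and 0.235 for model 5.

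**Figure D3:**
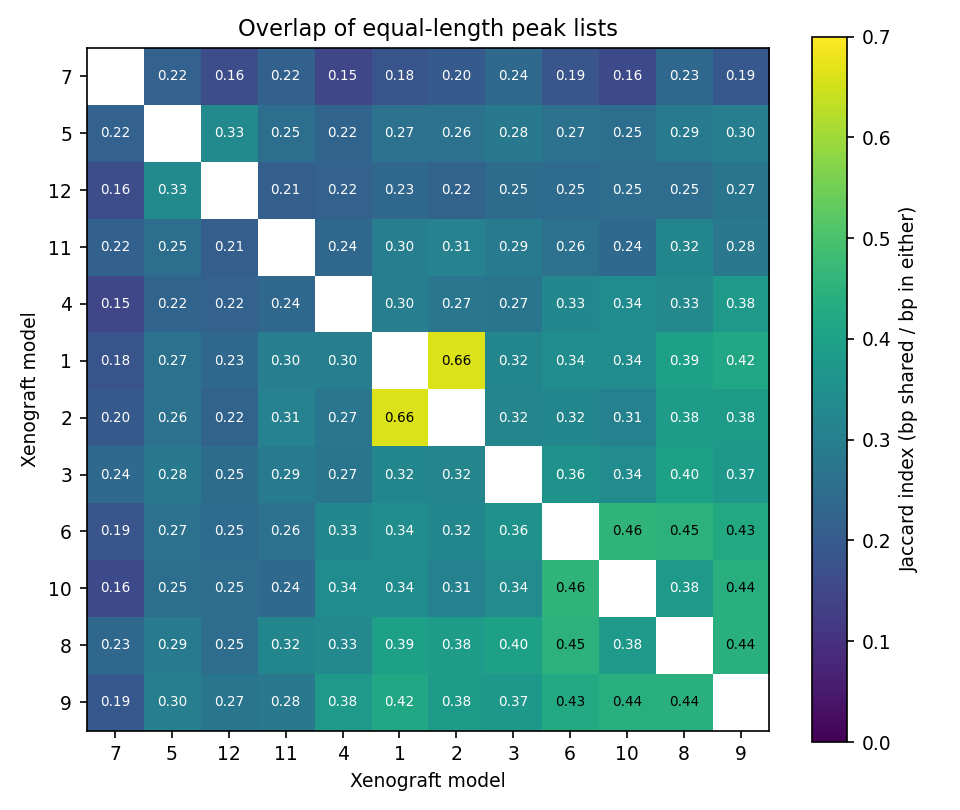
The colour and number in each cell give the Jaccard index of 2 xenograft models from peak lists of equal length, with models ordered by average-linkage clustering. Models 1 and 2 have the highest index, 0.663, and model 7, whose list covers the fewest base pairs, has the lowest mean index with the others, 0.194.

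Pairs sequenced in the same run were not more alike on average than other pairs. The mean Jaccard index was 0.294 ± 0.104 (SD, 25 pairs) within a run and 0.302 ± 0.078 (41 pairs) between runs. The difference of −0.007 was within the range given by reassigning runs to models (permutation test, two-sided, p = 0.817). Pairs share models, so these SDs are not of independent values. Run A holds model 7, whose indices were low. Without model 7 the difference was 0.005 (permutation test, two-sided, p = 0.865).

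Models 1 and 2 had the most regions to themselves, and models 5 and 12 the next most. Regions found in these models alone numbered 3664 for models 1 and 2, 2651 for models 5 and 12, which came from different runs, and 1056 for models 6 and 10. The next pair, models 3 and 10, had 830. The size of these excesses depended on the expected number. Fitted to the counts of all other pairs, the expected numbers were 40.2, 58.7 and 147.1, and the ratios 91.24 (95% interval 81.92 to 101.69), 45.16 (40.57 to 50.75) and 7.18 (6.45 to 7.97). That fit lowers the expectation of similar models, because a region that one of them shares with another model is not counted when the other has it too. In the alternative, each factor was fitted with the partner left out, and the 3 pairs with the highest ratios took no part in the fits. The expected numbers were then 677.8, 209.6 and 573.7 and the ratios 5.41, 12.65 and 1.84. Models 5 and 12 thus had the highest of the 3 ratios. Both changes were made together, so their effects cannot be told apart. A ratio of 1 is not the level of no excess in the first fit, and other pairs were not called.

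**Figure D4:**
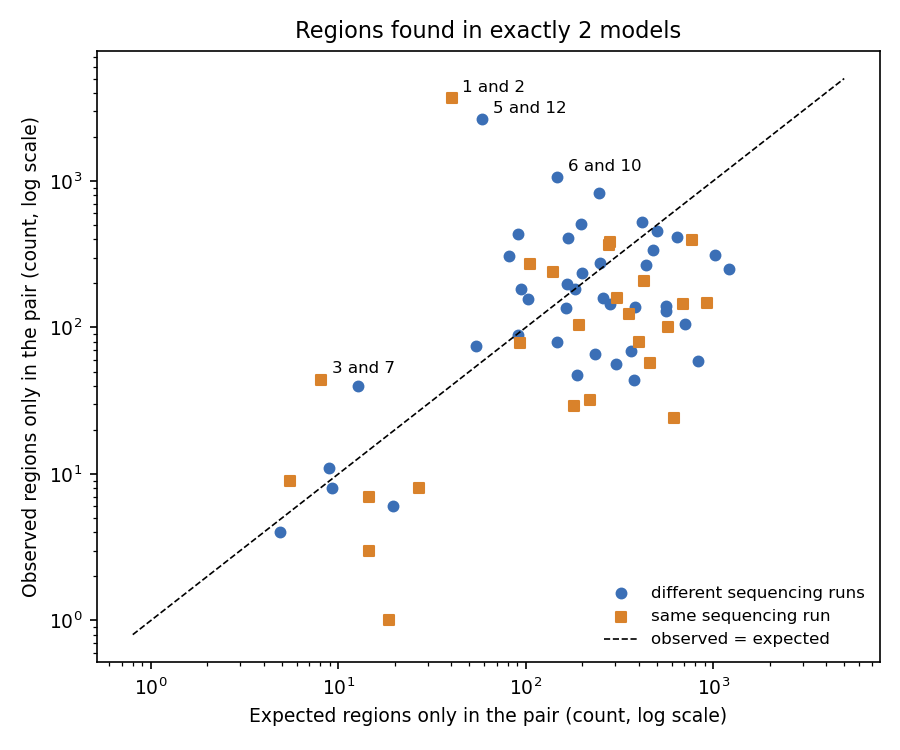
Each point is 1 of the 66 pairs of xenograft models, with the number of regions found only in that pair expected from a fit to all other pairs on the horizontal axis and the observed number on the vertical axis, both on log scales. Models 1 and 2 (3664 regions) and models 5 and 12 (2651 regions) lie farthest above the dashed line where both numbers are equal, in a fit that lowers the expectation of similar models.

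The number of peaks in a list was set against 3 other measures across the 12 models, and none of the relations passed the adjustment over the 3. Against the number of single-model regions, Pearson's r was 0.58 (permutation p = 0.0525, adjusted 0.096) and Spearman's rho 0.62 (permutation p = 0.0367, adjusted 0.11). Without models 7 and 11, the farthest from the median, r was 0.6 (permutation p = 0.0732), and within run A it was 0.55 (exact permutation p = 0.175, n = 7). Against the mean Jaccard index, r was 0.55 (permutation p = 0.064, adjusted 0.096) and rho 0.27 (permutation p = 0.405, adjusted 0.608). That r was −0.23 without models 7 and 11, so it rests on those models. Within run A, which includes model 7, r was 0.76 (exact permutation p = 0.0589, n = 7). Against the median fold, r was 0.19 (permutation p = 0.575, adjusted 0.575) and rho −0.02 (permutation p = 0.956, adjusted 0.956), with r at −0.18 without models 7 and 11 and at 0.0 within run A. Runs B and C held too few models for a value of their own.

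Of the 500 broad acetylated domains kept per model, 15 were common to all 12 tumours, and between 12 (model 2) and 270 (model 12) were kept in that model alone. The domains merged into 2448, of which 1368 (55.9%) were in 1 model's 500, 827 in 2 to 5 models and 253 (10.3%) in 6 or more. Among the domains in all 12 models, the one with most base pairs under peaks lay at chr22:46402433-46506611 (22q13.31), with 43.0 ± 17.7 kb (SD, n = 12) and a range from 16.6 to 65.1 kb. The domain at chr19:39127465-39228645 (19q13.2) had 29.4 ± 21.2 kb, that at chr6:26155615-26287094 (6p22.2) 28.3 ± 11.3 kb, and that at chr1:154928068-155067007 (1q21.3 to 1q22) 28.1 ± 12.3 kb. On chromosome 1, shared domains also lay at 156050518-156134920 (1q22, 20.0 ± 6.6 kb), 156630021-156723105 (1q23.1, 17.6 ± 9.0 kb), 234724726-234768164 (1q42.3, 15.7 ± 4.8 kb) and 149801924-149835009 (1q21.2, 15.5 ± 5.1 kb). The last of the 10 named were chr22:36719003-36791972 (22q12.3, 18.5 ± 8.1 kb) and chr6:27759264-27816747 (6p22.1, 15.3 ± 6.4 kb). The lowest value in a model was 1.7 kb at 19q13.2, 3.0 kb at 1q23.1, 3.3 kb at 22q12.3 and 4.3 kb at 6p22.1. These were of model 7, since every other model kept only domains of at least 4.9 kb. The place of these domains in all 12 models thus rests on the lower limit of model 7, 1.7 kb. Of the 10 named, 5 were not in all 12 models under another setting. With a joining distance of 5 kb, the domain at 1q21.2 was in 7 models, that at 6p22.1 in 9, and those at 19q13.2 and 1q23.1 in 11. With 300 domains per model, the domain at 1q23.1 was in 9 models, and those at 19q13.2 and 1q21.3 to 1q22 in 11. The number of domains in 6 or more models was 140 with 300 domains kept per model and 571 with 1000.

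Model 12 had the most single-model domains, 270, followed by model 7 with 229 and model 4 with 186. The 500 domains of model 7 reached down to 1.7 kb under peaks, where the smallest kept in the other models had 4.9 to 10.6 kb, so its count includes domains too small for the other lists. The fewest, 21 and 12, were in models 1 and 2. The longest-covered was in model 12 at chr5:14142267-14209215 (5p15.2), with 49.5 kb under peaks against at most 7.3 kb in another model. Model 11 had 42.3 kb at chr11:27296200-27389594 (11p14.1), against at most 3.5 kb elsewhere. Model 10 had 39.6 kb at chr7:76583021-76640258 (7q11.23), and model 4 had 35.4 kb at chr11:61299253-61396233 (11q12.2), against at most 8.1 and 6.8 kb. Model 5 had 32.3 kb at chr7:93996712-94056179 (7q21.3), against at most 9.6 kb. Model 6 had 27.6 kb at chr1:92183740-92245386 (1p22.1), and model 9 had 21.0 kb at chr11:34345024-34393869 (11p13). Model 8 had 15.8 kb at chr5:179592131-179608947 (5q35.3), and model 3 had 14.2 kb at chr8:47129285-47160418 (8q11.1). Model 7 had 7.9 kb at chr6:99272001-99293215 (6q16.1), where 1 other model had a peak. In models 1 and 2 such domains were barely their own. Model 1 had 13.4 kb at chr5:158605664-158637214 (5q33.3) where model 2 had 11 kb, and model 2 had 8.6 kb at chr2:102637863-102651303 (2q11.2) where model 1 had 8.1 kb. A single-model domain is thus one outside the 500 of every other model, which can still have peaks there.

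**Figure D5:**
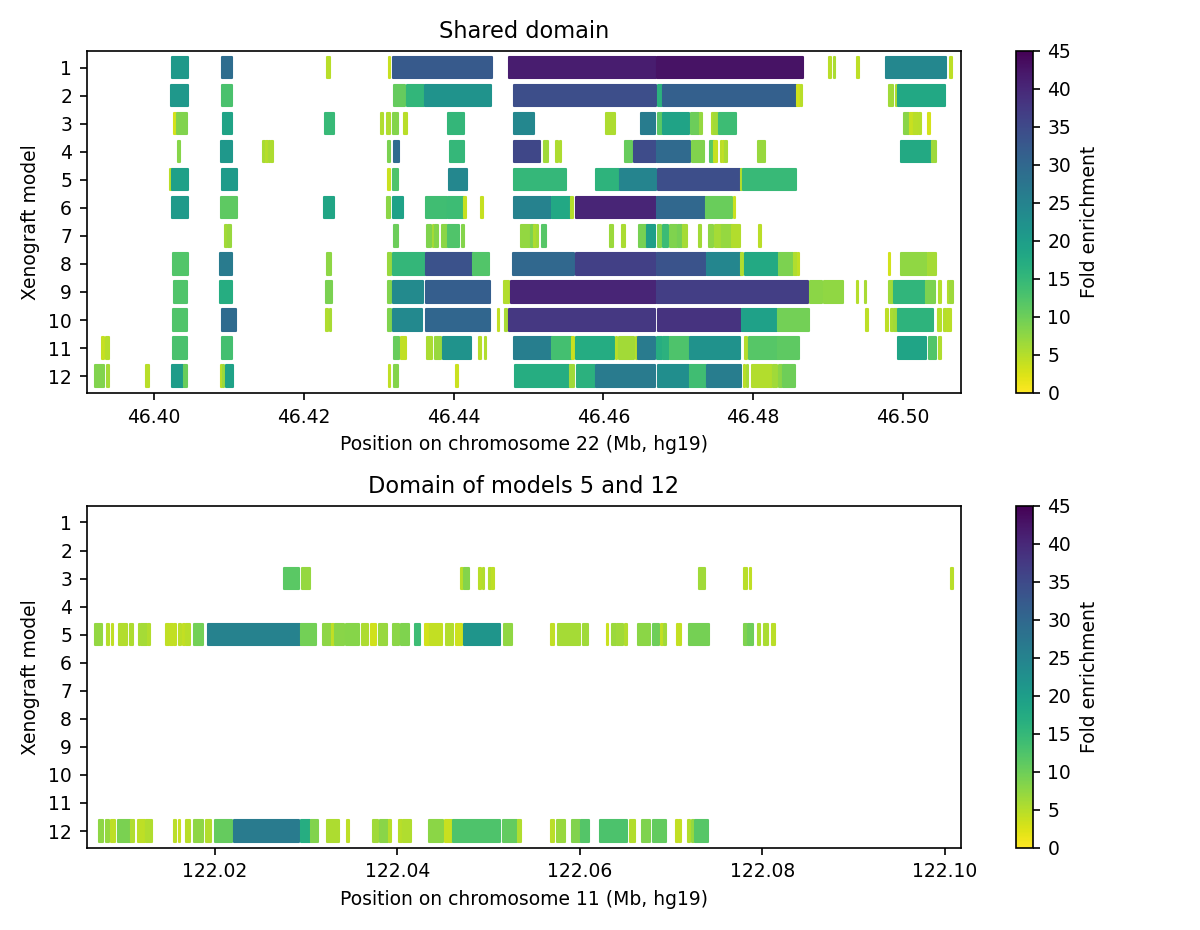
Bars give the H3K27ac peaks of each of the 12 xenograft models along hg19 coordinates in Mb, coloured by the fold enrichment in each list, for the domain in all 12 models on chromosome 22 (top) and the domain of models 5 and 12 on chromosome 11 (bottom), with the peaks in 20 kb on each side. All 12 models have peaks in the first, over 16.6 to 65.1 kb, though models 5, 6, 7 and 12 have none near its right end, and in the second only model 3 has peaks besides models 5 and 12.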

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

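Peaks on sequences outside chromosomes 1 to 22 and X were set aside in the comparisons and still carried signal, and no input list was used here to set a background. The 12 lists together held 4612 peaks on 9 alternate haplotype sequences, of which 4183 lay on 7 sequences of chromosome 6, and 645 peaks on 35 unplaced or unlocalised sequences. Alternate haplotype sequences repeat parts of the main chromosomes, so reads can be divided between copies, and counts per model are not given. The rule for samples far from the others covers groups of at most 10 samples and was not applied to the 12 models.

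The tests below of the shared run, of the calling threshold and of model 12 alone were chosen after the result was seen.

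Models 1 and 2 overlapped more than any other pair. Without model 2 the highest same-run index was 0.439, for models 9 and 10 of run C. That was below 0.459 for models 6 and 10, which came from different runs. In run A, which held models 1 and 2, the highest index without model 2 was 0.399, for models 3 and 8. These values argue against a shared sequencing run as the whole cause. Reads of one library in the other remain open. Over the 200 strongest regions that models 3 to 12 lack, the median fold in the other model was 0.66 of that in model 1 and 0.94 of that in model 2, with 198 and 199 called there, which argues against such reads by the bound of 0.5 set in advance. That reading was changed to open after the result was seen, because the bound rested on the strongest regions alone, and over all such regions 39.7% of the 9227 of model 1 and 67.4% of the 5438 of model 2 were called in both; no biological explanation was tested.

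Models 4 and 12 held 49.5% of the single-model regions. Peaks of a −log10 q under 5 as the whole cause are argued against. At 5 or more the smaller of their counts was still 2.21 times the highest count of another model. That filter kept on average 32142 of 38638 peaks per model, so weak peaks above it remain open as a cause. Single-model regions took 62.4% of the weakest 1000 peaks in model 4 and 56.1% in model 12, against 0.2% and 2.6% of the strongest. List length cannot be told apart for model 4, because in equal-length lists the smaller of the 2 counts, that of model 4, was 1.08 times the next, between the bounds of 1 and 1.5 set in advance. For model 12 the ratio was 1.76, which argues against list length as the whole cause there, although this split by model was made after 1.08 was seen. No biological explanation was tested, since the labels name no subgroup.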

How the results depend on the processing

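Leaving out model 7 was planned for the numbers of regions in all models and in 1 model and, with the next smallest list setting the length, for the overlap of pairs. The other settings that left out a model, and those that joined models 1 and 2, left out models 4 and 12 or used summit windows were chosen after the data were examined, as were all settings of the chromosome shares, peak strength and pair ratios, and the −log10 q setting of peaks per model. Among the main results, 74 values under other settings kept their direction and, for tests, their side of the threshold, or stayed within 1.5 times (counts) or 1 SD (other values), 9 moved and 6 changed sign. Regions in all 12 models numbered 2626 in equal-length lists and 116 with 50% of a region covered, both stricter by construction. Regions in 1 model numbered 14636 in equal-length lists and 49686 without models 4 and 12. Domains in 6 or more models numbered 140 with 300 kept per model and 571 with 1000. Chromosomes with a lower single-model share numbered 3 in equal-length lists, and those with a higher share 5 at a −log10 q of at least 5 and 2 in equal-length lists; the cause was not tested. The run difference was 0.003 with the next smallest list setting the length and ranged from −0.024 to 0.009 with each model left out. Leaving out each model gave 5306 to 7332 regions in all others, 63313 to 79852 in 1 model, a median index of 0.273 to 0.309 and 203 to 241 domains, within 1.5 times of the full set. The strongest minus the weakest peaks differed by 64.2 percentage points in their core share, by 62.4 at a −log10 q of at least 5 and by 54.2 in equal-length lists. Among named regions, domains and pairs, 37 values were the same and 12 moved, among them the pair ratios with summit windows (47.88 and 28.82) and with the partner left out. Not run for want of an hg19 annotation were the promoter share of regions, promoter peaks per gene list, the coherence, correlation and variability of gene lists, and their alternatives. Depth is unknown, so a region without a peak in a model, above all in model 7, is one not called there, not one shown to lack acetylation.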

Other observations

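The domains found only in a pair of models were examined after the pairs had been seen. The largest numbers were 76 for models 1 and 2, 40 for models 5 and 12, 21 for models 6 and 10, and 19 for models 6 and 8. The longest-covered domain of models 5 and 12 lay at chr11:122006910-122081339 (11q24.1), with between 41.6 and 45.2 kb under peaks and a highest fold of 26.4. There, 1 other model had peaks, over 5.1 kb. Models 5 and 12 also shared domains at chr17:48226331-48300430 (17q21.33), with 10.5 kb in one and 34.8 kb in the other, where 10 other models had peaks, over at most 6.8 kb. At chr11:12131572-12228946 (11p15.3) one had 6.1 kb and the other 25.5 kb, and another model had 6.6 kb, so that domain was not particular to the pair.

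The longest-covered domain of models 1 and 2 lay at chr3:158427140-158520515 (3q25.32), with 45 kb in one and 48.3 kb in the other, where no other model had more than 6.4 kb. At chr6:72074102-72131309 (6q13) they had between 43.3 and 45.6 kb, against at most 8.2 kb, and at chr9:14118485-14182589 (9p23) between 24.0 and 29.9 kb, against at most 7.0 kb. Models 6 and 10 shared a domain at chr3:43019128-43044090 (3p22.1) with between 17.2 and 20.1 kb, against at most 3.9 kb. At chr17:40501567-40584666 (17q21.2) they had 12.3 to 24.8 kb, against at most 10.9 kb. At chr1:150934561-150982005 (1q21.3) they had 13.2 to 19.3 kb and another model had 13.7 kb, so that domain was not particular to the pair.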
